A study of Mus musculus with 4 samples.

How the data were processed

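Seq-well single-cell RNA libraries were made from lineage-depleted bone marrow and spleen of mice with CBFB::MYH11 leukemia, per the labels, after 7 days of doxycycline at 3 ug/ml or of 5% sucrose as control. The deposited values are raw whole-number counts per gene and cell barcode of 12 bases, made by the authors and aligned to mm10 per the submitters' processing notes. The aligner, the counting tool, the barcode filter and whether molecular identifiers were collapsed are not given in the sources used here, so the values are called counts. The 4 files hold 22000, 22000, 22000 and 20000 barcodes for bone marrow control, bone marrow dox, spleen control and spleen dox, with 39447, 38415, 37460 and 38078 genes that have a count. Gene positions come from the GENCODE annotation of GRCm38.

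A barcode was kept as a cell with at least 500 counts, at least 300 genes and at most 20% of counts from genes of the mitochondrial genome. The kept cells held 56863470, 62970525, 71122080 and 156053209 counts, and their median share of mitochondrial counts was 10.5%, 7.58%, 5.44% and 3.53%. Scrublet (expected rate 5%) called 1, 1, 83 and 0 doublets. These are under 0.5% of the cells of each library, so the caller did not work on these data and its calls were removed only as an alternative. Of all counts in kept cells, the ribosomal RNA gene CT010467.1 took 11.3%, 11.1%, 12.3% and 13.2% and mitochondrial ribosomal RNA 9.06%, 6.58%, 6.77% and 3.26%.

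Counts of all kept cells of a library were summed and scaled to counts per 1000000 (CPM). With 1 library per group, a difference within a tissue or within a treatment could not be tested. A model of treatment with tissue as a block, which has 1 residual degree of freedom and takes the difference of the dox effects as error, was not fitted. Each log2 ratio of CPM has an exact 95% interval (Clopper-Pearson, conditional binomial). The difference of the 2 dox effects has a normal 95% interval from Poisson variances. All intervals cover counting error only, and reads of the same molecule would make them too narrow. Genes needed 100 counts in the 2 sums together, and a gene passed the size rule with a ratio of at least 2-fold and an interval that excluded no difference. The 5 comparisons were dox against control in each tissue, spleen against bone marrow under each treatment, and the difference of the dox effects.

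Genes were named by a rule: the 12 highest and 12 lowest by the interval end nearest 0, among genes of at least 100 CPM in the higher library, without mitochondrial and ribosomal protein genes, numbered Gm and Rik genes and pseudogenes, plus Cbfb, Myh11 and Runx1. Beside a list, the members with the largest ratios were named. Other members, such as Ifit2, S100a8, Cdkn1a, Bcl2, Car1 and, for the difference of the dox effects, Ms4a2 and Csf2rb, were chosen after their values were seen. The filters, the comparisons, the naming rule, the 30 gene lists and the 12 marker lists were written before the data were examined. Each list median was placed among 10000 random lists matched on expression in 20 bins, and a median outside percentiles 2.5 to 97.5 lay outside the random range. Random genes were drawn independently, whereas genes of a list can vary together. A percentile therefore does not give the chance of such a median between libraries. The ribosomal protein list was matched by prefix and also holds Rps6k kinases and pseudogenes. The genes Azu1, Ahsp and mt-Atp8 are not in the files and were not analysed here. The value of 1 gene of a list is not reported here.

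Cells of all libraries were clustered without batch correction (10000 counts per cell, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 0). A cluster was named when at least 3 markers of 1 list were raised by at least 1.5-fold at 20 CPM or more, at least 1 was among its 10 leading genes, the markers of all other lists together were fewer among those 10, and no other list had more raised markers. No cluster could be named as progenitor, so the comparison inside that class was not made. For shares of cells with RNA of a list, cells were thinned to 500 counts.

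Barcodes found in both spleen files, after a first base C was read as A, were left out of both files as an alternative chosen after the files were seen. Other alternatives were TMM and median-of-ratios scaling, minimums of 300 or 1000 counts per cell, no mitochondrial maximum, gene minimums of 30 or 300, every cell weighted alike, doublet calls removed, hemoglobin and ribosomal RNA left out of the totals, and, for clusters, resolutions 0.5 and 2 and thinning. The procedure was tested on simulated data with the depths of 4 comparisons. The intervals held the true ratio for 95.5%, 95.5%, 95.5% and 95.4% of genes, and the rule found 99%, 98%, 100% and 100% of genes simulated at log2 1.3. Between 0 and 2 unchanged genes passed, and 2.5%, 5%, 7% and 6% of random lists fell outside the random range. The simulated counts had independent Poisson error only, as the intervals assume. These values therefore check the calculation, and do not give the rate of false calls between real libraries.

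Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.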

Results

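Seq-well single-cell RNA sequencing, which captures cells and barcoded beads in nanowells, was applied to lineage-depleted cells of mice with leukemia driven by CBFB::MYH11, the fusion made by the inversion of chromosome 16. Mice received 5% sucrose as control or doxycycline (dox) at 3 ug/ml for 7 days, and bone marrow and spleen were taken. The series title says that leukemia cells needed the fusion to survive in spleen but not in bone marrow, a statement that was not tested here. The construct that doxycycline acts on is not given in the sources used here. Each tissue and treatment had 1 library, 4 in all, so differences have no replicate check and intervals cover counting error only. Total counts were 62284775 in bone marrow control, 65863368 in bone marrow dox, 75057931 in spleen control and 156357633 in spleen dox. After filtering, 10365, 16010, 19307 and 19735 cells remained in that order, with medians of 2761, 2014.5, 2497 and 5880 counts and 1188, 832, 1057 and 1810 genes per cell.

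The spleen files shared barcodes. After a first base C was read as A, 10820 barcodes were in both, where chance gives 38.9, and they carried 43.8% of the counts of the control file and 70.3% of those of the dox file. The expression of the shared barcodes in the control file was close to the dox file (SD of log2 ratios over genes 0.126 against the other dox barcodes) and far from the other control barcodes (0.751). Plek, for example, a signaling adaptor of blood cells, was at 25.5 CPM (counts scaled to a library sum of 1000000) in the shared barcodes of the control file, 286 in its other barcodes and 20.2 in the other barcodes of the dox file. Values from unshared barcodes (8745 cells in spleen control, 8990 in spleen dox) therefore stand beside most spleen values and are called unshared. Only exact matches were left out, so unshared control barcodes may still include some that belong to the dox file.

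**Figure D1:**
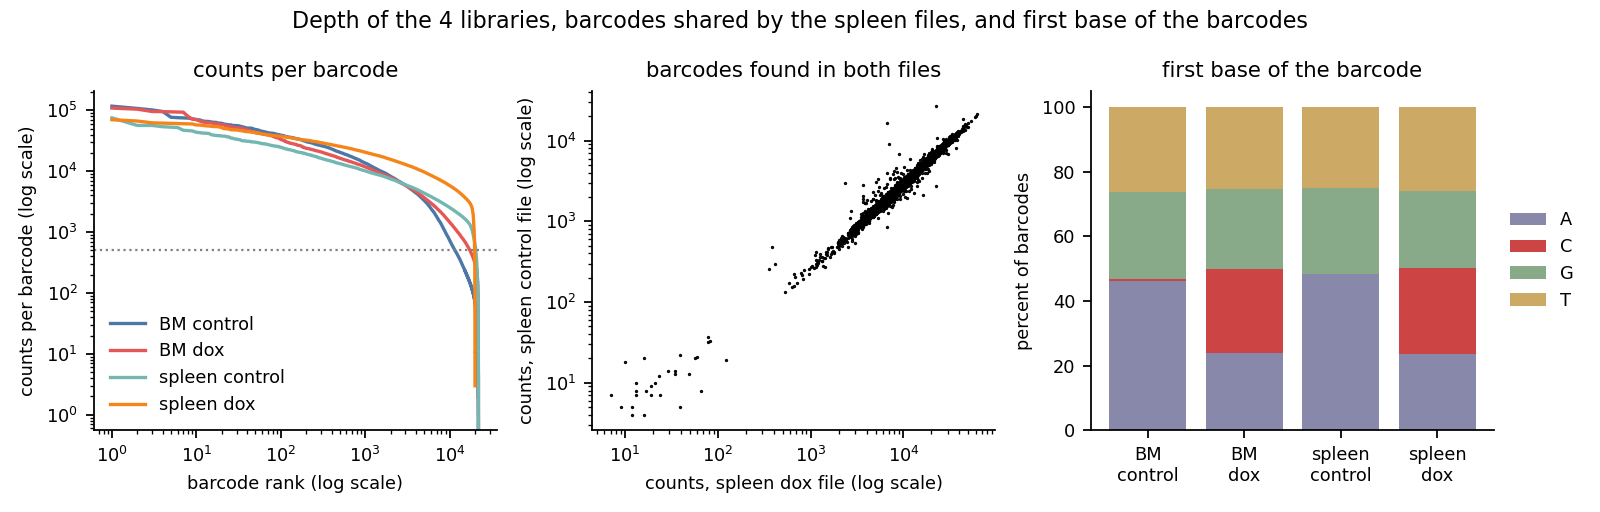
Counts per barcode against barcode rank for the 4 libraries (left, both axes log, dotted line at the minimum of 500 counts), counts of barcodes found in both spleen files (middle, both axes log, barcodes starting with G or T) and percent of barcodes by first base (right, stacked bars). Shared barcodes follow 1 line, with a median of 0.290 counts in the control file per count in the dox file, and barcodes starting with C make up 26.25% and 26.65% of the dox files but 0.436% and 0.0182% of the control files.

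Clustering of 65417 cells gave 12 clusters, of which 4 could be named from marker lists: clusters 0 and 3 were erythroid-like, cluster 7 neutrophil-like and cluster 9 B cell-like. Cluster 5, which held 0.241% of bone marrow control and 32.5% of bone marrow dox cells, stayed unnamed because granule and monocyte markers stood beside S100a8, S100a9 and Camp among its leading genes, and so did cluster 11, where F13a1 and Ccr2 stood beside Mpo and Prtn3. Of the 4761 cells of cluster 7, 4657 came from bone marrow control, so that library and cell type are not separate in it. With resolution 2 only 1.97% of bone marrow control cells lay in neutrophil-like clusters and after thinning 20.8%, against 44.9% here. Unnamed clusters then held 96.9% and 70.1% of them, against 53.4% here. Shares of named clusters thus also follow how many clusters met the naming rule. These were 6 of 22 with resolution 2, 7 of 50 after thinning and 3 of 12 with doublet calls removed. Cluster 7 also had Plek at 353 CPM, as clusters 4 and 6 did (283 and 364). The erythroid-like clusters held 0.289% of cells in bone marrow control (exact 95% interval 0.195 to 0.413), 3.35% in bone marrow dox (3.07 to 3.64), 38.05% in spleen control (37.4 to 38.7; unshared 8.10%) and 50.3% in spleen dox (49.6 to 51.0; unshared 57.0%). Clusters 2, 8 and 10 had at least as many erythroid markers as markers of any other type but none among their leading genes, stayed unnamed and held another 0.820%, 3.85%, 19.3% (unshared 5.52%) and 43.4% (unshared 36.4%). The intervals leave out the choice of clustering, which moved the shares far more: after thinning the erythroid-like shares in spleen control and spleen dox were 7.82% and 11.9%, and with doublet calls removed 25.1% and 20.9%, the opposite order. These shares are not compared between libraries because hemoglobin RNA itself differed. Hemoglobin RNA took 0.962%, 13.02%, 9.15% (unshared 2.69%) and 17.2% (unshared 18.9%) of the counts in the 4 libraries, and after thinning to 500 counts it was found in 88.2% of bone marrow control cells, 99.9% of bone marrow dox cells and 99.98% of spleen dox cells. RNA of the neutrophil list was found in 63.3% of thinned bone marrow control cells (62.4 to 64.2; 84.9% unthinned) and 75.99% of bone marrow dox cells (75.3 to 76.7; 94.6% unthinned), but in 2.81% of unshared spleen control (11.2%) and 1.75% of unshared spleen dox cells (8.16%).

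In bone marrow, the lists of erythroid genes, interferon-induced genes, p53 targets and stress-response genes had higher median ratios of dox over control than matched random lists. Some interferon genes and p53 targets were lower. A group of genes led by Mrvi1, Slc18a2 and Plek had less RNA in dox. Hbb-bt, an adult beta globin gene, was 40.2-fold higher, from 513 to 20615 CPM (log2 ratio 5.33, interval 5.31 to 5.35). Mrvi1, which encodes a substrate of cGMP-dependent kinase, was lower, from 213 to 12.3 CPM (log2 -4.11, interval -4.22 to -4.00). Both parts of the core-binding factor were lower in dox: Cbfb, the fusion's 5' partner, went from 79.00 to 42.3 CPM (log2 -0.90, interval -0.97 to -0.83) and Runx1, its DNA-binding partner, from 152 to 80.2 (log2 -0.93, interval -0.98 to -0.88). Neither gene passed the 2-fold size rule, and the median log2 ratio of all genes was -0.33.

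The counts have no entry for the fusion transcript, and they do not show whether Cbfb counts include any RNA of the fused allele. Cbfb (ENSMUSG00000031885) lies on chromosome 8 at 105170674 to 105217989 and Myh11 (ENSMUSG00000018830) on chromosome 16 at 14194535 to 14291372 of GRCm38. Myh11 had 2, 12, 6 and 9 counts in bone marrow control, bone marrow dox, spleen control and spleen dox, too few for a ratio.

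Of 12669 genes with at least 100 counts in the bone marrow libraries, 637 were at least 2-fold higher and 1264 at least 2-fold lower in dox, with counting intervals that excluded no difference. TMM scaling moves all log2 ratios up by 0.24 (median of all genes from -0.33 to -0.09) and gave 847 higher and 702 lower, and median-of-ratios scaling 833 and 730. The genes named as higher were Hbb-bt, Hba-a2 (log2 4.10), Hbb-bs (3.98), Alas2, the first enzyme of heme synthesis in red cells (3.68), Tmcc2 (3.61) and Ube2o, a ubiquitin ligase of maturing reticulocytes (3.58). They also included Cldn13 (3.45), the glucose transporter Slc2a1 (3.43), the Rh-associated glycoprotein Rhag (3.44), Lpcat1 (3.34), and the interferon-induced Ifit1 (3.65) and Isg15 (3.61). Beside Mrvi1, the genes named as lower were the monoamine transporter Slc18a2 (-3.37), Rab27b (-2.83), the adaptors Lat (-2.42) and Lcp2 (-2.23), Gcnt2 (-2.28), Plek (-2.25), Sptan1 (-2.21), Gnb4 (-2.20), the transcription factor Fli1 (-2.15), Tiam1 (-2.03) and the X-inactivation RNA Xist (-2.02).

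Of 20 erythroid genes measured in bone marrow, 13 were at least 2-fold higher in dox and none lower (median log2 1.45), above all of 10000 random lists of matched expression (percentile 100). Of 22 interferon genes, 10 were higher, such as Oasl2 (2.45), Rtp4 (1.99) and Irf7 (1.98), and Rsad2 (-1.83) and Ifit2 (-1.49) were lower (median 0.88, percentile 100). Of 16 p53 targets, 6 were higher, among them Eda2r (3.49), Sesn2 (2.30) and the cell cycle inhibitor Cdkn1a (1.59, from 67.3 to 202 CPM), and Pmaip1 was lower at -1.98 (median 0.60, percentile 100). Of 18 genes of the integrated stress and unfolded protein responses, 5 were higher, led by Chac1 (2.92), Atf5 (2.77) and Trib3 (2.49) (median 0.54, percentile 100). Medians were also above the random range for lymphoid genes (0.38, percentile 99.97, Gzma 2.03), granule proteins (0.32, percentile 99.9) and nuclear-retained RNAs (0.68, percentile 99.3). In the last list Malat1 was higher at 2.06, while Xist, named above, was lower. Genes of the mitochondrial genome also had a median above the random range (0.30, percentile 99.03). That median counts each gene alike, and the share of mitochondrial RNA in all counts was lower in dox, with a median per cell of 7.58% against 10.5% and mitochondrial ribosomal RNA at 6.58% against 9.06%.

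Lower in bone marrow dox were 4 of 21 leukemia stem cell and growth receptor genes, namely Il1rap (-1.44), Meis1 (-1.22), the IL-33 receptor Il1rl1 (-1.03) and Cd34 (-1.03), while Ly6a was higher at 1.11 (median -0.65, percentile 0.7). The platelet list had 4 of 7 genes lower, such as Treml1 (-3.88) and Itga2b (-1.69), while Pf4 was higher at 1.90 (median -1.69, percentile 0). With a gene minimum of 30 the direction of this list turned, to a median of 0.89 relative to all genes. The myeloid transcription factor list had a median of -0.68 (percentile 1.77) and the neutrophil list one of -0.60 (percentile 0.38), with Retnlg at -1.45 and S100a8 at 0.04. The BCL2 family had 4 of 18 genes lower, among them Bcl2 (-1.12), while Bcl2l1, which encodes BCL-XL, was higher at 1.81 (median -0.63, percentile 1.02). Medians of all other lists lay inside the random range: fusion and RUNX genes (-0.46), monocyte and macrophage genes (-0.34), mast cell and basophil genes (0.02), stroma and endothelium (-0.21), S phase (-0.25) and G2/M phase (-0.21). So did niche adhesion (-0.52), MHC class I (-0.12) and class II (-0.31), immediate early and heat shock (-0.20), NF-kB inflammation (-0.06), MYC and ribosome biogenesis (-0.20), glycolysis (-0.33), nuclear OXPHOS (-0.18), cholesterol synthesis (-0.52), housekeeping (-0.36) and ribosomal proteins (-0.22). Of these lists, stroma and endothelium, G2/M phase, MHC class I, immediate early and heat shock, NF-kB inflammation, MYC and ribosome biogenesis, nuclear OXPHOS and ribosomal proteins lay above 0 with TMM or median-of-ratios scaling. These differences are not assigned to cell types here. Hemoglobin RNA was found in most cells of both bone marrow libraries, and Plek and Mrvi1, both lower in dox, are among the leading genes of clusters 4 and 6, so that the sizes of those clusters follow the difference itself. Clusters 4 and 6 held 26.2% and 18.7% of bone marrow control but 2.41% and 1.22% of bone marrow dox cells. In unshared barcodes they held 54.1% and 31.0% of spleen control but 0.556% and 0.323% of spleen dox cells. Cluster 1, which stayed unnamed, held 5.92% of bone marrow control and 52.6% of bone marrow dox cells.

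In spleen, the medians of erythroid and interferon-induced genes were likewise higher in dox, and Plek, Srgn, Il1rl1, Ms4a2 and Gata2 were lower. The differences were larger in unshared barcodes. Hbb-bt was at log2 1.06 (unshared 3.47, from 3965 to 43979.9 CPM). Plek was at -2.96 (interval -3.02 to -2.91; unshared -3.82, from 286 to 20.2 CPM). Cbfb was at -0.95 (interval -1.02 to -0.89; unshared -1.56, from 65.4 to 22.1 CPM) and Runx1 at -1.01 (interval -1.06 to -0.96; unshared -1.58).

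Of 12477 genes, 135 were at least 2-fold higher and 1156 lower in spleen dox (635 and 2575 of 10761 unshared). TMM scaling moves all log2 ratios up by 0.45 (0.55 unshared) and gave 813 higher and 544 lower (1215 and 1052 unshared), and median-of-ratios scaling 815 and 540. The genes named as higher were Hbb-bt, Hba-a2 (1.04, unshared 2.84), the red cell pyruvate kinase Pklr (1.03, unshared 3.29), the membrane protein Stom (1.02, unshared 2.81) and Rab3il1 (0.98, unshared 3.16). They also included Tmcc2 (0.96, unshared 2.83), the anion exchanger Slc4a1 (0.96, unshared 2.60), Alas2 (0.92, unshared 2.84), Tent5c (0.95, unshared 2.57), Add2 (0.96, unshared 2.91), Ube2l6 (0.93, unshared 2.07) and Oas3 (0.94, unshared 2.28). Named as lower, beside Plek, were S100a10 (-2.51, unshared -3.23), the proteoglycan core Srgn (-2.26, unshared -2.99), Slc22a3 (-2.18, unshared -3.09), Crip1 (-2.07, unshared -2.81) and Il1rl1 (-1.95, unshared -2.69). Rnf130 (-1.94, unshared -2.77), Sptbn1 (-1.74, unshared -2.46), the IgE receptor subunit Ms4a2 (-1.72, unshared -2.42), Dock8 (-1.56, unshared -2.24), the transcription factor Gata2 (-1.54, unshared -2.18) and Laptm5 (-1.55, unshared -2.25) were named as well. By the same rule in unshared barcodes, Mrvi1 (-6.62) and Slc18a2 (-5.98) were named as well, both also named as lower in bone marrow.

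**Figure D2:**
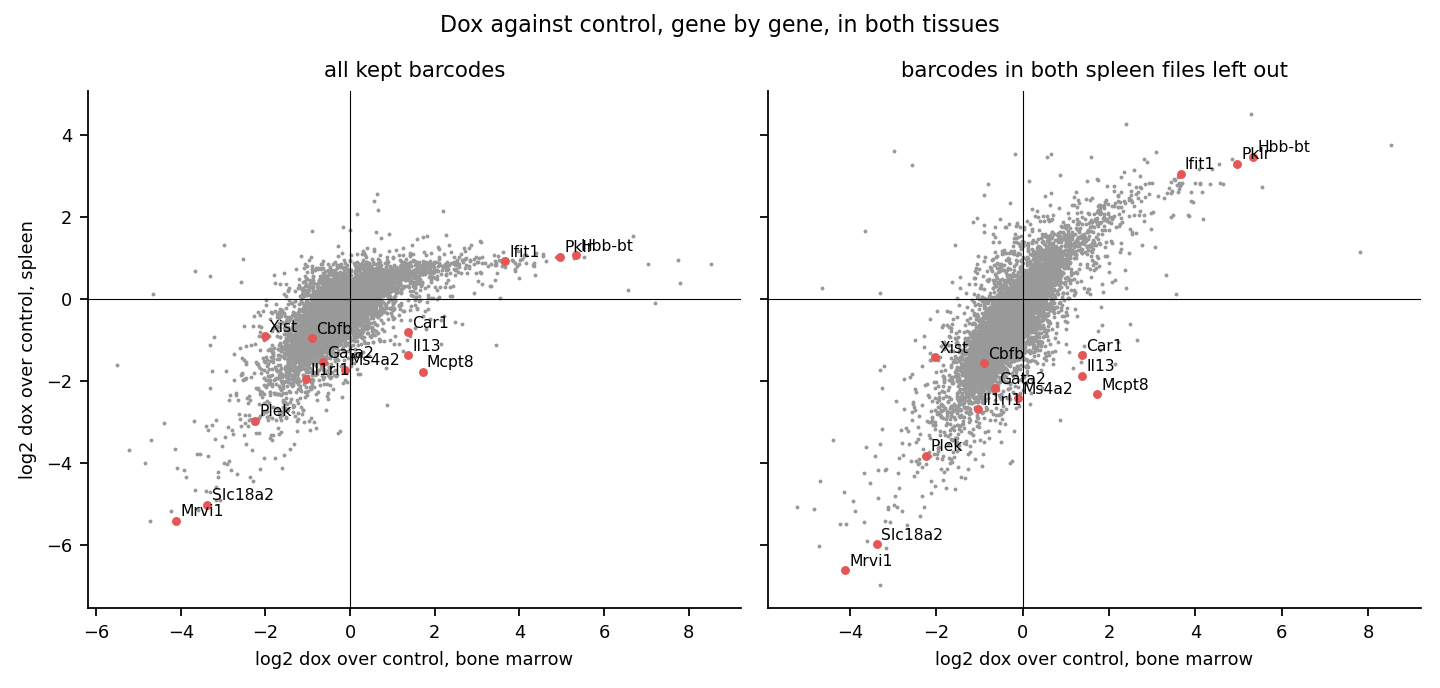
Each point is a gene (red where labelled), with the log2 ratio of dox over control in bone marrow (x axis) and in spleen (y axis), for all kept barcodes (left) and without barcodes found in both spleen files (right). Of the labelled genes, Hbb-bt, Pklr and Ifit1 lie at the upper right and Plek, Slc18a2 and Mrvi1 at the lower left in both panels, and Hbb-bt in spleen moves from 1.06 to 3.47.

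Erythroid genes had a median of 0.64 (percentile 100; unshared 1.57, percentile 100) in spleen, with 14 of 20 at least 2-fold higher in unshared barcodes and Car1 lower at -1.38. Interferon genes had one of 0.64 (percentile 100; unshared 1.5, percentile 100), with 16 of 21 higher in unshared barcodes, such as Ifit1 (3.05). Medians above the random range were also found for monocyte and macrophage genes, at 0.49 (percentile 100; unshared 0.77, percentile 100), and lymphoid genes, at 0.46 (percentile 100; unshared 1.07, percentile 100). The integrated stress list was at 0.25 (percentile 99.99; unshared 0.45, percentile 100). MHC class II was at 0.36 (percentile 99.9; unshared 0.86, percentile 99.9). The p53 targets were at 0.13 (percentile 99.95; unshared 0.15, percentile 99.9), with Cdkn1a at 0.45 (unshared 1.06). The mast cell and basophil list had 7 of 9 genes lower (unshared 7 of 7), such as the protease Cpa3 (-3.22, unshared -3.94) and Hdc, which makes histamine (-2.90, unshared -3.79), and a median of -1.72 (percentile 0; unshared -2.55, percentile 0). The fusion and RUNX list had 4 of 10 genes lower (unshared 6 of 10), with Runx2 at -2.06 (unshared -2.71) and a median of -0.90 (percentile 0; unshared -1.57, percentile 0). In the leukemia receptor list 6 of 18 genes were lower (unshared 8 of 11), such as Meis1 (-1.97, unshared -2.75) and Csf2rb2, a beta chain of the IL-3 receptor (-2.08, unshared -2.65), and the median was -0.70 (percentile 0.06; unshared -1.40, percentile 0.04).

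Genes of the mitochondrial genome had a median of -0.59 (percentile 0.02; unshared -1.03, percentile 0.145) in spleen and glycolysis genes one of -0.48 (percentile 0.21; unshared -0.93, percentile 0.1). The BCL2 family was at -0.47 (percentile 1.97; unshared -0.85, percentile 4.58), the unshared value inside the random range, with Bcl2 at -1.41 (unshared -2.07) and Bcl2l1 at 0.90 (unshared 2.11). The platelet list had a median of -0.49 (percentile 17.9; unshared -2.61, percentile 0.03) and stroma and endothelium genes one of -0.87 (percentile 2.59; unshared -2.27, percentile 0.35). Nuclear OXPHOS, at -0.27 (percentile 2; unshared -0.54, percentile 4.32), and ribosomal proteins, at -0.31 (percentile 0; unshared -0.67, percentile 0.01), had medians below 0, and those of all barcodes lay above 0 with TMM scaling. Cell cycle lists had medians near 0, at 0.02 for S phase and 0.01 for G2/M phase (unshared -0.05 and -0.04). The median of all genes was lower, at -0.24 (unshared -0.52), so both lists lay above it. The mean of the S phase list was just below 0, and both unshared cell cycle medians lay above 0 with TMM scaling.

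With control treatment, the spleen library had far less RNA of neutrophil and granule genes than the bone marrow library and more erythroid RNA. Retnlg, a secreted protein of neutrophils, had 10233 counts in bone marrow and 38 in spleen (log2 -8.40, unshared -8.51). S100a9 was at -6.66 (unshared -6.19) and S100a8 at -6.61 (unshared -6.09). Hbb-bt was higher in spleen at 5.25 (unshared 2.95). In unshared control barcodes hemoglobin was at 180435, 91538.5 and 172381 CPM in clusters 0, 2 and 3, but 14070 and 12619 in clusters 4 and 6. Clusters 0, 2 and 3 of unshared spleen dox had 206949, 123032 and 220287. Barcodes of the dox file remaining in this set cannot be told apart from erythroid cells of the control spleen.

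Of 12317 genes, 324 were at least 2-fold higher and 1778 lower in control spleen (70 and 1154 of 11977 unshared). TMM scaling moves all log2 ratios up by 0.33 and gave 521 higher and 1207 lower (87 and 1081 unshared), and median-of-ratios scaling 563 and 1152. Also named as higher were Add2 (4.33, unshared 2.31), Ifit1 (3.78, unshared 1.66), the mitochondrial iron importer Slc25a37 (3.77, unshared 1.84), Slc2a1 (3.71, unshared 1.70) and Rhag (3.65, unshared 1.85). Named too were Alas2 (3.46, unshared 1.58), Hbb-bs (3.44, unshared 1.63), Hba-a2 (3.10, unshared 1.41), Tmcc2 (3.09, unshared 1.27), Ube2o (3.06, unshared 1.25) and Lpcat1 (3.04, unshared 1.21). Also named as lower were Camp (-6.56, unshared -6.11), the eosinophil major basic protein Prg2 (-6.36, unshared -5.87), Ltf (-6.23, unshared -5.72), Ngp (-5.97, unshared -5.47), Lcn2 (-5.92, unshared -5.40), Anxa1 (-5.91, unshared -5.50), the protease Prtn3 (-5.84, unshared -5.84), Lyz2 (-5.63, unshared -5.81) and Chil3 (-5.54, unshared -4.90). Cbfb was at -0.71 (unshared -0.27) and Runx1 at -0.77 (unshared -0.27).

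All 19 neutrophil genes were at least 2-fold lower in control spleen (median -6.56, unshared -6.14), as were 11 of 12 granule protein genes (-5.01, unshared -5.16). The same held for 11 of 14 myeloid transcription factors (-2.34, unshared -2.03) and 14 of 20 leukemia receptor genes (-1.75, unshared -1.94, with Cd93 at -5.15, unshared -5.05). Also lower were 12 of 18 monocyte and macrophage genes (-2.08, unshared -2.74) and 11 of 18 niche adhesion genes (-1.64, unshared -1.09), with the marrow homing receptor Cxcr4 at -5.20 (unshared -4.58). These lists were at percentile 0. Lymphoid genes had a median of -1.03 (percentile 1.57; unshared -1.95, percentile 0.02) and NF-kB inflammation genes one of -0.98 (percentile 0.27; unshared -0.52, percentile 0.775). Erythroid genes were higher, at a median of 1.52 (percentile 100; unshared 0.58, percentile 100). The interferon list had a median of 0.35 (percentile 100; unshared -0.19, percentile 16.9). S phase genes, at 0.15 (percentile 99.98; unshared 0.13, percentile 99.99), and cholesterol synthesis, at -0.05 (percentile 98.6; unshared 0.28, percentile 100), lay above their random ranges. MYC and ribosome biogenesis, at 0.02 (percentile 99.2; unshared 0.25, percentile 100), did so too. G2/M phase did not, with a median of -0.08 and a mean of 0.04, and the medians of G2/M phase and cholesterol synthesis in all barcodes lay above 0 with TMM scaling.

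With dox, spleen again had much less neutrophil and granule RNA than bone marrow. S100a8 was at log2 -6.97 (unshared -6.20) and Mpo, the myeloperoxidase of granules, at -5.32 (unshared -5.28). Mast cell and basophil genes were lower as well, all 12 of those measured (median -3.29; unshared 10 of 11 and -2.98), such as the basophil protease Mcpt8 (-5.84, unshared -5.72). Pklr was the gene named first as higher, at 3.00 (unshared 2.93).

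Of 13028 genes, 267 were at least 2-fold higher and 2560 lower in dox spleen (196 and 2317 of 11843 unshared). TMM scaling moves all log2 ratios up by 0.54 (0.35 unshared) and gave 1031 higher and 1501 lower (412 and 1583 unshared), and median-of-ratios scaling 1240 and 1416. Also named as higher were the calcium pump Atp2b4 (1.83, unshared 1.76), Rab3il1 (1.78, unshared 1.75), Add2 (1.77, unshared 1.70), Slc25a37 (1.68, unshared 1.67) and the GATA1 cofactor Zfpm1 (1.64, unshared 1.57). So were Cd24a (1.38, unshared 1.35), Mnd1 (1.37, unshared 1.38), Arrb1 (1.34, unshared 1.26), Apeh (1.32, unshared 1.23), Trim10 (1.27, unshared 1.27) and Hemgn (1.25, unshared 1.20). Also named as lower were S100a9 (-6.86, unshared -6.10), Ngp (-6.46, unshared -5.71), Prtn3 (-6.44, unshared -6.31), Camp (-6.43, unshared -5.64), Ltf (-6.25, unshared -5.47), Ctsg (-5.63, unshared -5.85), Ly6c2 (-5.09, unshared -5.37), Lyz2 (-4.89, unshared -4.87), Prg2 (-4.68, unshared -3.36) and Plac8 (-4.19, unshared -4.35). Cbfb was at -0.76 (unshared -0.94) and Runx1 at -0.85 (unshared -0.92).

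All 19 neutrophil genes were lower in dox spleen (median -6.37, unshared -5.67), as were 11 of 12 granule protein genes (-5.25, unshared -5.09), 19 of 21 leukemia receptor genes (-2.04, unshared -2.08) and 11 of 18 niche adhesion genes (-2.16, unshared -2.15, with Cxcr4 at -3.85, unshared -3.70), all at percentile 0. Genes of the mitochondrial genome were at -1.03 (percentile 0; unshared -1.06, percentile 0) and nuclear-retained RNAs at -2.08 (percentile 0.01; unshared -2.005, percentile 0.01), with Malat1 at -2.08 (unshared -1.92). Erythroid genes, at 0.55 (percentile 100; unshared 0.52, percentile 100), S phase genes, at 0.41 (percentile 100; unshared 0.31, percentile 100), and G2/M phase genes, at 0.25 (percentile 100; unshared 0.10, percentile 99.7), had medians above the random range. The interferon list had a median of 0.08 and a mean of -0.31, and the housekeeping list a median of 0.15 and a mean of -0.07. Medians of the BCL2 family (-0.58, unshared -0.63), MHC class I (-0.55, unshared -0.60) and glycolysis (-0.59, unshared -0.67) were below the random range and lay above 0 with median-of-ratios scaling.

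**Figure D3:**
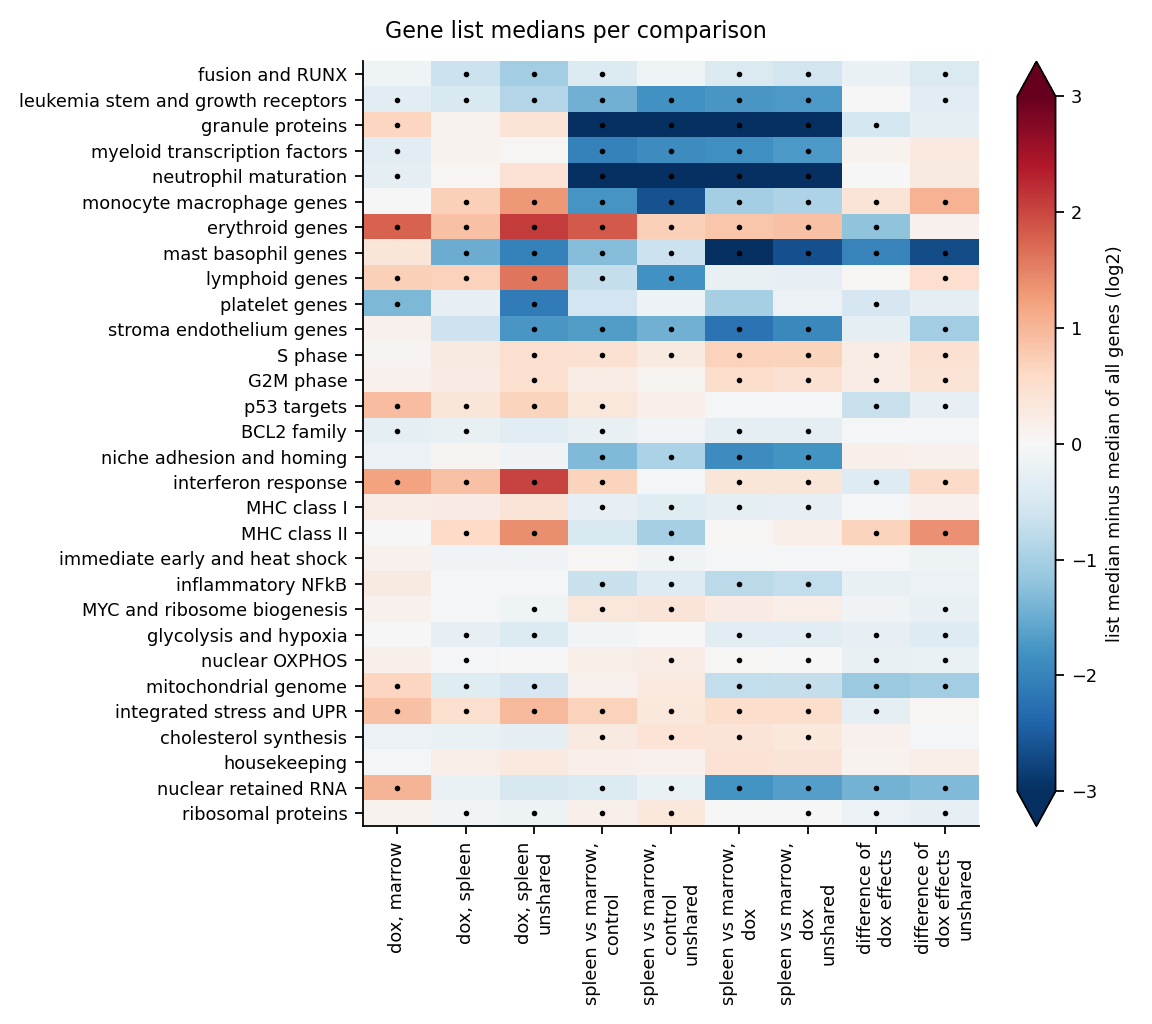
Median log2 ratio of each gene list minus the median of all genes, in the 5 comparisons (columns, spleen comparisons also without shared barcodes; colors end at -3 and 3; dots mark medians outside the middle 95% of 10000 random lists). Neutrophil and granule lists are darkest in the spleen against bone marrow columns, and erythroid genes are red in the dox against control columns.

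The difference of the dox effects, spleen minus bone marrow, asks whether dox went with another change in spleen than in bone marrow. Mast cell and basophil genes stood out: 7 of 9 were at least 2-fold lower in spleen relative to bone marrow (unshared 7 of 7), with a median of -1.97 (percentile 0; unshared -2.87, percentile 0). Ms4a2, for example, was at -0.11 in bone marrow (above 0 with TMM scaling) and -1.72 in spleen (difference -1.61, unshared -2.31), and Csf2rb at 0.07 and -1.39 (difference -1.47, unshared -2.09). Cbfb differed little with all barcodes (difference -0.05, interval -0.15 to 0.04; above 0 with TMM scaling) and was lower in spleen when unshared (-0.66), as was Runx1 (-0.08, above 0 with TMM scaling; unshared -0.65).

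Of 11908 genes, 232 had a difference of at least 2-fold upward and 578 downward (208 and 817 of 10720 unshared). TMM scaling moves all differences up by 0.21 (0.26 unshared) and gave 391 and 397 (350 and 486 unshared), and median-of-ratios scaling 413 and 384. Differences named as lower were Hbb-bt (-4.27, unshared -1.86), Pklr (-3.94, unshared -1.67), Hbb-bs (-3.13, unshared -1.15), Hba-a2 (-3.06, unshared -1.26), Alas2 (-2.76, unshared -0.84) and Isg15 (-2.76, unshared -0.94). They also included Ifit1 (-2.73, unshared -0.60), Slc2a1 (-2.60, unshared -0.58), Rab3il1 (-3.09, unshared -0.91), Ube2o (-2.68, unshared -0.80), Tmcc2 (-2.65, unshared -0.78) and Rhag (-2.60, unshared -0.87). Differences named as higher were Prg2 (1.69, unshared 2.52), Mnd1 (1.34, unshared 1.13), Selenbp1 (1.26, unshared 1.01), the immunoglobulin gene Ighm (1.17, unshared 2.07) and Xist (1.12, unshared 0.60). They also included the leukocyte phosphatase Ptprc (1.01, unshared 1.64), Actg1 (0.98, unshared 0.57), the survival factor Mcl1 (0.69, unshared 0.54), Ppp1cc (0.82, unshared 0.35), Nop53 (0.79, unshared 0.66), H1f3 (0.73, unshared 0.56) and Retnlg (1.42). Of 11909 genes measured in both dox comparisons, 51 were at least 2-fold higher in both tissues, 685 lower in both and 9 opposite (7 higher in bone marrow and lower in spleen, 2 the other way). With TMM scaling 392 were higher in both, 325 lower in both, and 3 and 7 opposite, so the balance between higher and lower depends on the scaling. Unshared, without TMM, these were 337, 858, 12 and 7 of 10720.

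The erythroid list had a median difference of -1.17 (percentile 0; unshared -0.06, percentile 79.7). With TMM scaling the unshared erythroid median lay above 0. The interferon list was at -0.35 (percentile 0; unshared 0.37, percentile 100) and so changed direction without the shared barcodes. Xist, named above with a higher difference, belongs to the nuclear-retained list and went against its median. The mitochondrial genome, at -1.09 (percentile 0; unshared -1.24, percentile 0), nuclear-retained RNAs, at -1.38 (percentile 0; unshared -1.52, percentile 0.01), and p53 targets, at -0.63 (percentile 0; unshared -0.45, percentile 2.21), were below the random range either way. S phase, at 0.25 (percentile 100; unshared 0.25, percentile 100), G2/M phase, at 0.25 (percentile 99.99; unshared 0.22, percentile 100), monocyte and macrophage genes, at 0.43 (percentile 100; unshared 0.86, percentile 100), and MHC class II, at 0.70 (percentile 99.98; unshared 1.17, percentile 100), were above it. The leukemia receptor list had a median of 0.02 (percentile 47.1; unshared -0.51, percentile 2.39) and a mean of -0.04, and the fusion and RUNX list one of -0.17 (percentile 4.3; unshared -0.62, percentile 0.35) that lay above 0 with TMM scaling.

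**Figure D4:**
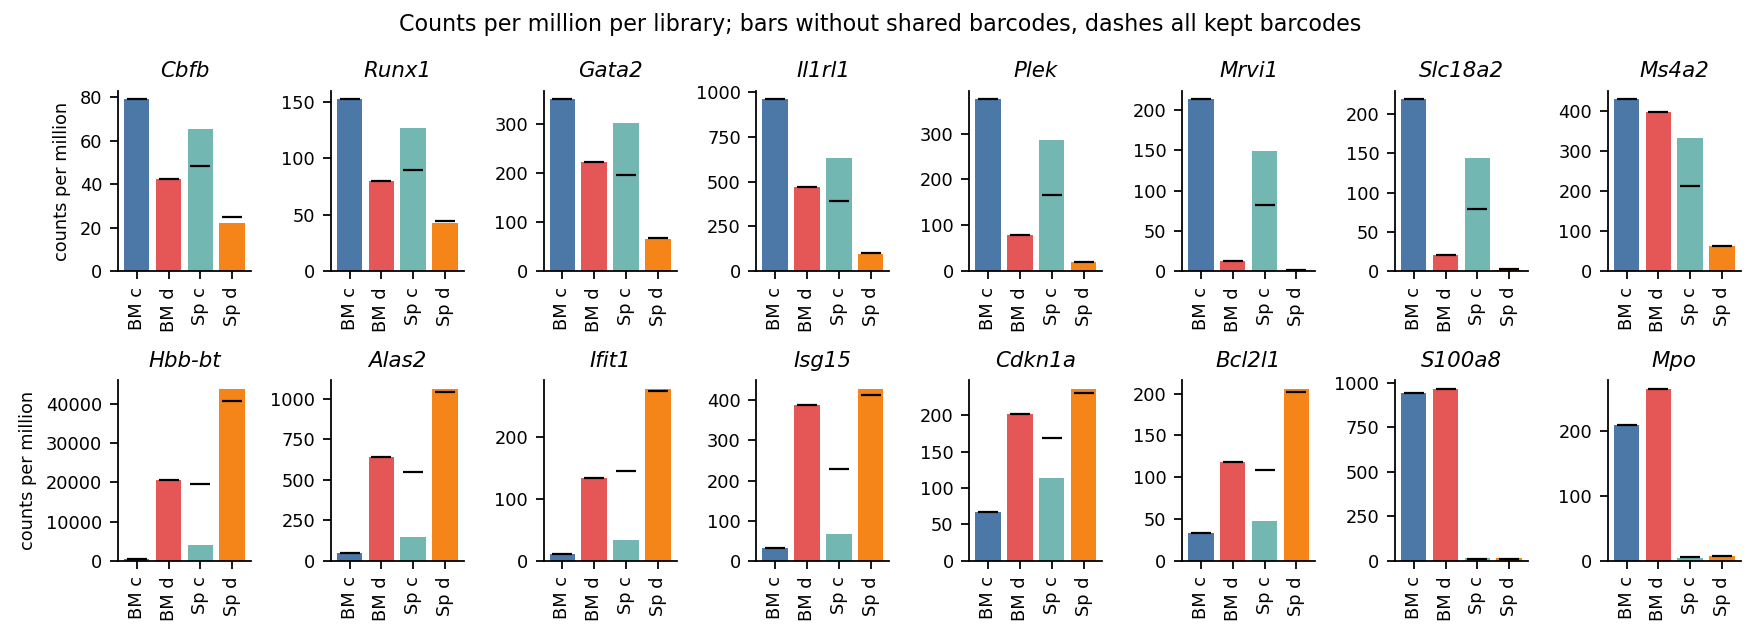
CPM (y axes) of 16 genes in bone marrow control (BM c), bone marrow dox (BM d), spleen control (Sp c) and spleen dox (Sp d). Bars leave out barcodes found in both spleen files and dashes include them; Cbfb goes from 79.00 to 42.3 in bone marrow and from 65.4 to 22.1 in unshared spleen barcodes, with no replicate or error bar.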

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

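All tests in this part were chosen only after the result was seen. The spleen files hold 10820 barcodes in common, which stood out because no comparison uses barcode sequence. Il13, which encodes a cytokine of type 2 immunity, was higher with dox in bone marrow (log2 1.36) and lower in spleen (-1.37, interval -1.83 to -0.92; unshared -1.87), a difference of -2.73. Mcpt8, a basophil protease, was likewise higher in bone marrow (1.71) and lower in spleen (-1.77, interval -2.24 to -1.31; unshared -2.32), a difference of -3.48. The median of the mitochondrial genome list relative to all genes was 0.64 in bone marrow and -0.35 in spleen (unshared -0.51), a difference of -0.99. That median counts each gene alike, and the share of mitochondrial RNA per cell was lower with dox in both tissues (median 10.5% to 7.58% in bone marrow, 5.44% to 3.53% in spleen), as was mitochondrial ribosomal RNA (9.06% to 6.58%, and 6.77% to 3.26%). The gene and list values stood out because their directions differed between the tissues, and with 1 library per group the differences were not tested.

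Of the barcodes of the spleen control file, 49.2% are also in the spleen dox file. Chance recurrence is argued against, since the shared barcodes are 278-fold more than it gives, and so are beads of the control array read into the dox file, since the shared barcodes there were closer to the other dox barcodes than to the other control barcodes (difference in SD -0.698). Beads of the dox array read into the control file may be the source: the shared barcodes of the control file were closer to the dox barcodes than to the control file's own barcodes (difference in SD -0.624), and their counts were a steady 0.290 of those in the dox file (5th to 95th percentile 0.255 to 0.330). No biological explanation was tested, and the step at which this happened stays open.

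Most erythroid genes were higher, and Mrvi1, Plek and Il1rl1 lower, in both dox libraries. Dilution by hemoglobin and ribosomal RNA as the whole cause is argued against, since it lowers every other gene by a log2 of 0.18 in bone marrow, 0.11 in spleen and 0.27 in unshared spleen barcodes, less than the fall of these genes. Leaving those counts out of the totals moves every ratio up by that amount, so fewer genes pass as lower and more as higher. Lower genes were then 803 in place of 1264 in bone marrow and 940 in place of 1156 in spleen. Higher genes were 803 in place of 637 and 240 in place of 135. RNA of erythroid cells may lie in barcodes of other cells. Hemoglobin in immunoglobulin and monocyte clusters was 0.848 of that in other clusters in bone marrow dox and 0.978 in unshared spleen dox. Of the 576 such cells in bone marrow dox, 521 were B cell-like. B cell-like cells there were 57 with resolution 0.5, 81 with resolution 2, 386 after thinning and 570 with doublet calls removed. These reference cells thus depend on the clustering. In the lowest cluster of bone marrow dox hemoglobin was 0.390 of the library level, so an even spread as the whole source stays open there. In unshared spleen dox it was 0.651, which decides nothing. Apart from the B cell-like cluster, clusters of at least 100 cells there were erythroid-like or matched the erythroid markers best. The labels name a lineage depletion, and whether it removed erythroid cells is not given. A lower share of leukemic cells stays open. The erythroid median was above the lymphoid one by 1.07 in bone marrow, within the spread of the genes. In unshared spleen barcodes it was above by 0.49, just under the bound set. The neutrophil list, which was tried first, lay 2.05 and 1.64 below the erythroid one, and the monocyte and macrophage list 1.79 and 0.80 below. Both gaps in bone marrow were beyond the spread of the genes. So was the neutrophil gap in unshared spleen (SD 1.15 for erythroid and 0.50 for neutrophil genes), but not the monocyte gap there. The gaps beyond the spread go against a lower share alone unless the leukemic cells, which are myeloid, express these genes themselves. Separate handling of the dox and control libraries cannot be told apart from the treatment, since barcodes starting with C reach at most 0.436% in the control files, and an effect of doxycycline stays open.

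RNA of neutrophil genes was found in most barcodes of both bone marrow libraries. An even spread of neutrophil RNA over all barcodes as the whole source is argued against, since the list in the lowest cluster was at 0.0590 of the library level in bone marrow control (0.130 in counts per cell) and 0.0573 in bone marrow dox (0.211 in counts per cell; cluster 8 had 0.0653 and, in counts per cell, 0.110). Neutrophil RNA in barcodes of other cells may be part of the source in bone marrow dox. The median in immunoglobulin and monocyte clusters there was 1.09 of that in other clusters. Of these 576 reference cells, 521 were B cell-like, a number that depends on the clustering, as given above. In bone marrow control the ratio was 0.352 and decides nothing. S100a8 was among the abundant genes of the neutrophil RNA. The lineage depletion named in the labels acts on cells and not on free RNA. A low amount spread over all barcodes, and expression in the leukemic cells themselves, were not tested and stay open.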

How the results depend on the processing

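The alternatives that leave out shared barcodes, or hemoglobin and ribosomal RNA, were chosen after seeing the data. Replicates could not be paired because each group has 1 library, a model with tissue as a block was not fitted, and the comparison within a leukemic progenitor class was not run because no cluster could be named so. Genes past the size rule are given as higher and lower, and where a count is missing it stayed within 1.5-fold of that in the report.

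In bone marrow dox against control, higher genes were 1104 with a gene minimum of 30 and 395 with 300. Lower genes were 702 with TMM, 730 with median-of-ratios and 803 without hemoglobin and ribosomal RNA. In spleen, higher genes were 813 with TMM, 815 with median-of-ratios, 265 and 67 with minimums of 30 and 300, 635 unshared, 1215 unshared with TMM, 883 with shared barcodes left out of control only, and 240 without hemoglobin and ribosomal RNA. Lower genes were 544 with TMM, 540 with median-of-ratios, 1869 with a minimum of 30, 2575 unshared and 2482 with control only.

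In control spleen against bone marrow, higher genes were 521 with TMM, 563 with median-of-ratios, 70 unshared (and 70 with control only) and 87 unshared with TMM. Lower genes were 1152 with median-of-ratios, 2866 and 1052 with minimums of 30 and 300, 1154 unshared (and 1154 with control only) and 1081 unshared with TMM. With dox, higher genes were 1031 with TMM, 1240 with median-of-ratios and 412 unshared with TMM. Lower genes were 1501 with TMM, 1416 with median-of-ratios, 4685 and 1462 with minimums of 30 and 300, and 1583 unshared with TMM. For the difference of the dox effects, higher genes were 391 with TMM, 413 with median-of-ratios, 414 and 90 with minimums of 30 and 300, and 350 unshared with TMM. Lower genes were 384 with median-of-ratios, 1238 and 342 with minimums of 30 and 300, and 893 with control only. Gene minimums change how many genes are tested and scaling adds a constant to each ratio. For the other settings the cause was not tested.

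Without shared barcodes, 8745 spleen control and 8990 spleen dox cells were left. The percent of cells in erythroid-like clusters was 0.172 in bone marrow control, 2.62 in bone marrow dox and 40.1 in spleen control with at least 1000 counts. With resolution 0.5 it was 4.597 in bone marrow dox, 45.04 in spleen control and 65.8 in spleen dox, and with resolution 2 it was 2.505, 23.7 and 27.9. After thinning it was 0.145, 0.962, 7.82 and 11.9 in the 4 libraries, and with doublet calls removed 0.174, 1.94, 25.1 and 20.9. Unshared, it was 8.10 in spleen control and 57.0 in spleen dox. Shares from another clustering also follow how many of its clusters met the naming rule.

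List medians relative to all genes changed sign in these cases, and the cause was not tested. The platelet list in bone marrow was at 0.89 with a gene minimum of 30. The ribosomal list in spleen dox against control was at 0.033 with cells weighted alike. Nuclear OXPHOS in spleen against bone marrow with dox was at -0.026 with a minimum of 300. Interferon genes in control spleen against bone marrow were at -0.057 unshared, with or without TMM, and with control only. In the difference of the dox effects, unshared with or without TMM, erythroid genes were at 0.13, interferon genes at 0.56 and integrated stress genes at 0.068, and with control only at 0.056, 0.53 and 0.047.

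Over 30 lists and 5 comparisons, 88 list medians lay outside the random range. Of these, 87 kept their direction relative to all genes with a gene minimum of 30, with one of 300 and with cells weighted alike. TMM and median-of-ratios cannot change these values. Of 75 in the spleen comparisons, 71 did so without shared barcodes. Of 130 values of named genes, 128 kept their direction with TMM (Cbfb and Runx1 in the difference did not), and 103 of 103 without shared barcodes, where 74 of 83 stayed past 2-fold. The other 9 were all in the difference of the dox effects, where 9 of 18 stayed past it (8 of 18 with TMM). With cells weighted alike, 101 of 108 stayed past 2-fold, but only 12 of 17 in spleen dox against control. Of the genes past the rule in spleen dox against control, 67 higher and 985 lower were past it in both sets of barcodes. Myh11 had too few counts for a ratio.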

Other observations

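The test in this part was chosen only after the result was seen. Barcodes starting with C made up 26.25% of bone marrow dox and 26.65% of spleen dox barcodes but 0.436% of bone marrow control and 0.0182% of spleen control barcodes, while A took 46.3% and 48.4% in the control files and 23.8% and 23.5% in the dox files. Other pairs of libraries shared between 117 and 226 barcodes as written. After a first base C was read as A they shared between 128 and 268, where chance gives 38.3 to 42.8. In the pairs of spleen barcodes that start with G or T, 5914 in number, the log totals had a correlation of 0.987 over barcodes, which are not replicates of the libraries. The profiles of the same barcode in the 2 files correlated with a median of 0.201 over genes, against -0.0024 for shuffled partners.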
